A study of Mus musculus with 40 samples.

How the data were processed

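Total RNA from Ba/F3 clones that carry an inducible PI3K or PKB was amplified, coupled to Cy3 or Cy5 and hybridized by the submitters to spotted mouse arrays, per the labels. Of the 40 arrays, 20 belong to each line. Each holds 1 time point (15, 30, 60, 120 or 240 min) against the t0 RNA of the same replicate series, so the 5 arrays of a series share 1 of the 8 t0 RNAs. There are 4 series per line. In series 1 and 3 the time point is in Cy5 and in series 2 and 4 in Cy3, and direction was taken from these labels. The lowest correlation between 2 arrays of the same orientation was -0.38, between a PI3K and a PKB array of 15 min with different t0 RNAs.

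The deposited scanner files give the intensity of each spot and of its local background in 2 colours. Channel 1 tracked the authors' Cy5 column on all 40 arrays. The authors' normalized files hold an intensity per channel whose mean log2 equals that of the scanned signals to within 7.1e-06, so the authors changed the ratio and subtracted no background. The deposited table of values is the log2 ratio of these normalized channels, time point over t0, to within 5e-06. The normalization method, scanner and software are not given in the sources used here. Values were recomputed from the scanner files. Per array 95.3% to 97.2% of the probes exceeded background plus 2 SD in at least 1 channel (77.7% to 95.9% in Cy5 and 93.7% to 97.2% in Cy3), and 5 to 120 spots were saturated (60000 units or more). The recomputed ratios, with the dye effect of each probe still in them, correlated with the deposited log2 ratios at r = 0.321 to 0.882 per array. In the deposited ratios the dye effects had an SD across probes of 0.067 in each line, against 0.257 and 0.243 in the recomputed ones. These r values therefore do not measure the agreement of the changes over time alone.

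Of 34992 spots, 3223 control spots were left out. The other 31769 probes were all tested, without a filter on dim probes, and 26000 of them carry a gene symbol. Old symbols were brought up to date against mouse gene names, which gave 17865 genes. No coordinates were used. Background was corrected with limma normexp (offset 50), and ratios were normalized within each array by loess. All 40 arrays entered 1 linear fit (limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table) with a coefficient for each of the 10 groups and 1 dye effect per probe. The residual degrees of freedom were 29, and 33.9 after moderation of the variances. Tests were two-sided and adjusted by Benjamini-Hochberg over all probes, separately for each comparison. The comparisons were each group against t0, any change over the 5 times of a line (F test), PI3K minus PKB at each time, the probes called the same way in both lines at 240 min, and 240 min against 15 min within a line. The t0 RNA cancels in the last. The median SE of a log2 ratio was 0.0625, and 0.0884 for a difference. SDs, values per array and signs use the ratios of single arrays after removal of the fitted dye effect. The dye effects had SDs across probes of 0.257 in the PI3K line and 0.243 in the PKB line when fitted for each line, with r = 0.839 between lines.

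The 25 gene lists were written from textbook knowledge. They were tested with camera, limma's competitive gene set test, at a preset correlation between genes of 0.01 and with an estimated correlation, and with fry, on the brightest probe of each gene, adjusted over the 25 lists. An adjusted p without further note is that of the preset correlation, and "estimated" marks the other. Counts of list members use calls over all probes or, where stated, p-values adjusted over the list alone. The samples, comparisons, lists, alternatives and the choice of genes to name were fixed before the data were examined. Genes named are those called, with the same sign on 4 of 4 arrays and a signal above background on all 4. They are the 12 highest and 12 lowest of each line at 240 min, the 4 and 4 at each earlier time, the 5 and 5 of the difference at 240 min (2 and 2 earlier, without the rule on signs) and the 8 and 8 shared by both lines. To these were added the 4 members of each list with the smallest adjusted p, Glul, Pik3ca, Akt1 and Esr1, and all FOXO, glutamine and autophagy genes called in both lines. Not all of these are printed. Where a gene has several probes, the brightest is given. The values of Myc and Dusp6 in the lines at 60 min in the account of the lists, and the 6 genes of the plot of time courses, were chosen after their values were seen.

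The test was tried on simulated data with the spread, dye effects and correlation within series of the measured arrays and with changes of known size. At a log2 change of 0.3, 49 of 67 probes were called (73.1%), at 0.5, 65 of 67 (97.0%), and at 1, 66 of 66. Of the probes left unchanged 15 were called. The alternatives were no background correction, an offset of 16, print-tip loess, median centring, scaling between arrays, the deposited log2 ratios, a filter on dim probes, no dye effect, blocks for the replicate series, fits of 1 line or 1 group alone, a 1.5-fold threshold, and leaving out each replicate. A dye effect for each line, the use of 240 min against 15 min on the lists, and all alternatives on the medians of the G1 and S phase, G2 and M phase, ribosome biogenesis and glycolysis lists were added after the data were seen. Metabolites, protein and autophagic flux were not analysed here.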

Results

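The arrays followed mRNA levels in Ba/F3 cells, a mouse pro-B cell line that needs the cytokine interleukin-3 to grow, after a kinase of the PI3K pathway had been switched on. In one clonal line the kinase was the membrane-targeted catalytic subunit of phosphoinositide 3-kinase (PI3K), the enzyme that makes the lipid messenger to which protein kinase B is recruited. In the other it was a membrane-targeted form of protein kinase B itself (PKB, also called AKT). Both were fused to the hormone-binding domain of the oestrogen receptor, which 4-hydroxytamoxifen (4-OHT) activates. RNA was taken before 4-OHT (t0) and 15, 30, 60, 120 and 240 min after it. The series concerns glutamine metabolism, autophagy and the FOXO transcription factors, which PKB phosphorylates and keeps out of the nucleus.

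Each of the 40 dual-colour arrays compared the RNA of 1 time point with the t0 RNA of the same replicate series. There were 4 series per line and so 4 arrays per line and time point, 2 with the time point in Cy5 and 2 with it in Cy3. The submitters describe the replicates as independent. Neither cells kept without 4-OHT for the same times nor cells without a fusion protein were among the samples, so each value is a change since t0 in that line. Median spot signals were 80.4 to 207 units in Cy5 and 106 to 162 units in Cy3 over median local backgrounds of 45 to 62 units. Per array, 95.3% to 97.2% of the gene probes stood above background in at least 1 channel. Values are log2 ratios of time point over t0 with the SE of the fit (n = 4 arrays per line and time point), and the number of arrays limits their precision. Calls are adjusted p-values under 0.05 from limma over 31769 probes. A fit with no dye effect leaves these values unchanged and counts the differences between dyes as error, since each group holds both orientations equally. It ended 61 of the calls of named genes, not all of which are listed as such.

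After 240 min of PI3K activation the highest mRNA was Hspa8, a constitutive heat shock chaperone, at 3.94-fold its t0 level (log2 ratio 1.98 ± 0.065). Srm, which makes the polyamine spermidine, followed at 1.91 ± 0.060. Next were Uhrf1, which maintains DNA methylation at replication forks (1.83 ± 0.079), and the chromatin remodeller Hells (1.80 ± 0.080). The alpha tubulin Tuba4a (1.74 ± 0.048), the respiratory electron carrier Cycs (1.62 ± 0.13), the translation initiation factor Eif5 (1.55 ± 0.065) and the replication clamp Pcna (1.44 ± 0.054) rose too. So did 2810026P18Rik (1.64 ± 0.058), Cdca7, a cell-division-associated gene (1.60 ± 0.063), Gm16286 (1.44 ± 0.050) and Timm8a1, a chaperone of mitochondrial protein import (1.40 ± 0.056). The lowest was Ypel3, a growth suppressor, at -1.85 ± 0.062, a 3.6-fold fall. Below t0 were also the linker histone Hist1h1c (-1.51 ± 0.099), Cmas, which activates sialic acid (-1.47 ± 0.034), the endocytic scaffold Itsn1 (-1.39 ± 0.071), the tetraspanin Tspan8 (-1.34 ± 0.077) and the transcriptional corepressor Cir1 (-1.34 ± 0.047). The chemokine Ccl9 (-1.29 ± 0.077), the repressor Hbp1 (-1.13 ± 0.069), the lipid-droplet enzyme Hsd17b11 (-1.11 ± 0.10), the nocturnin gene Ccrn4l (-1.11 ± 0.18) and the ubiquitin ligase Rnf125 (-1.11 ± 0.092) were further down-regulated genes. The adjusted p of these genes ran from 1.1e-26 for Cmas to 9.8e-06 for Ccrn4l. In all, limma called 2293 probes higher and 2204 lower, of which 426 and 206 moved by at least 1.5-fold. With median centring 2056 were higher and 1368 lower. Of the 5 Itsn1 probes none but the brightest was called, and a second, dimmer Ccrn4l probe rose (0.33, adjusted p = 0.00013).

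Genes of cell growth and of the first phases of the cell cycle rose as groups at 240 min of PI3K activation. In the list of MYC targets and ribosome biogenesis, 28 of 40 measured genes rose and 0 fell, and 31 rose when adjusted over the list alone. Besides Srm these included Bop1, a factor of ribosomal RNA maturation (1.13 ± 0.044), Dkc1, the pseudouridine synthase of small nucleolar particles (0.93 ± 0.046), and Wdr74 (0.77 ± 0.042). The list's median was 0.54 (camera, limma's competitive gene set test, adjusted p = 6.5e-30, and 1.3e-06 with an estimated correlation). Of 29 genes of the G1 and S phases, 24 rose and 0 fell (26 and 0 adjusted over the list alone, median 0.69, adjusted p = 7.7e-33, estimated 2.8e-09). Beyond Pcna, the replicative helicase subunits Mcm4 (1.37 ± 0.052) and Mcm3 (1.27 ± 0.053) and the licensing factor Cdt1 (1.31 ± 0.053) led it. Genes of the G2 and M phases went the other way, with 19 of 26 lower and 0 higher (20 and 1 adjusted over the list alone). Their median was -0.22 (adjusted p = 1.4e-10, estimated 0.00015). Examples were the spindle proteins Nusap1 (-0.90 ± 0.052), Tpx2 (-0.61 ± 0.057) and Hmmr (-0.47 ± 0.051) and the mitotic cyclin Ccnb2 (-0.64 ± 0.055). Chaperones of the unfolded protein response and heat shock list rose in 13 of 24 cases and fell in 1 (15 and 1 adjusted over the list alone, median 0.35, adjusted p = 2.1e-10, estimated 0.00015). After Hspa8 came Hsph1 (1.37 ± 0.070), the cytosolic Hsp90aa1 (1.20 ± 0.064) and the Hsp70 co-chaperone Dnajb1 (0.70 ± 0.042).

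The largest changes since t0 in the PKB line at 240 min were falls. Dusp6, the phosphatase that inactivates ERK, was lowest at -1.98 ± 0.10, a 3.95-fold fall. After it came Ypel3 (-1.86 ± 0.062), the thrombin receptor F2r (-1.78 ± 0.058), the pro-apoptotic Bbc3, also called PUMA (-1.56 ± 0.086), Tcp11l2 (-1.50 ± 0.081), Hbp1 (-1.47 ± 0.069), the mucin Muc20 (-1.43 ± 0.049) and the ETS transcription factor Etv5 (-1.37 ± 0.10). The glycolytic enzyme Pfkl (-1.29 ± 0.057), Hmha1 (-1.26 ± 0.051), Hist1h1c (-1.25 ± 0.099) and the glucose transporter Slc2a3 (-1.23 ± 0.063) completed the 12 lowest. Pfkl (-1.18) and Hist1h1c stood near these values already at 15 min, so a property of the t0 RNA cannot be told from a fall. The highest was the growth factor Fgf15 at 1.30 ± 0.082 (2.47-fold), then the dynein light chain Dynll1 (1.16 ± 0.061), Cycs (1.12 ± 0.13), the complex I assembly factor Ndufaf4 (1.02 ± 0.064) and the chaperones Hsph1 (1.02 ± 0.070), Hspa8 (0.99 ± 0.065) and Hspa5 (0.99 ± 0.073), the last of the endoplasmic reticulum. The tubulins Tubb2c (0.97 ± 0.052) and Tuba4a (0.95 ± 0.048), Cdr2 (0.93 ± 0.087), Psmc3ip (0.91 ± 0.10) and Mid1ip1, an activator of fatty acid synthesis (0.91 ± 0.099), were the others. Their adjusted p ran from 5.9e-22 for Ypel3 to 2.3e-08 for Cycs. In all, 2209 probes rose and 1946 fell, 153 and 166 of them by at least 1.5-fold. With each array centred on its median in place of loess, 1958 were higher and 885 lower.

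Genes of glycolysis and of the hypoxia response were lower than at t0 in the PKB line at 240 min. Of 22 genes of glycolysis and glucose uptake, 11 were lower and 0 higher (11 and 0 adjusted over the list alone, median -0.23, adjusted p = 2.3e-12, estimated 0.00022). With Pfkl and Slc2a3 stood phosphoglycerate kinase Pgk1 (-0.69 ± 0.050) and the enolase Eno1 (-0.66 ± 0.062). Of 19 hypoxia response genes, 7 were lower and 0 higher (8 and 1 adjusted over the list alone, median -0.060, adjusted p = 1.7e-05, estimated 0.0083). These included the stress-response gene Ndrg1 (-1.23 ± 0.074), the mitophagy receptor Bnip3 (-1.21 ± 0.083), the MYC antagonist Mxi1 (-0.78 ± 0.060) and the cytokine Mif (-0.52 ± 0.045). In the PI3K line glycolysis genes had a median of 0.045, with 4 higher and 2 lower, 5 and 2 adjusted over the list alone (adjusted p = 0.31). The hypoxia list there held 3 higher and 4 lower, 4 and 5 adjusted over the list alone (median 0.0071, adjusted p = 0.64).

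Oxidative phosphorylation genes rose after PKB activation, 13 of 28 with 0 lower (17 and 0 adjusted over the list alone, median 0.18, adjusted p = 6.2e-09, estimated 3.6e-05). Next to Cycs were the ATP synthase subunit Atp5g1 (0.50 ± 0.064), the complex I subunit Ndufv2 (0.29 ± 0.045) and the complex II subunit Sdhd (0.18 ± 0.036). Median centring ended the calls of Ndufv2 (0.34, adjusted p = 0.066) and Sdhd (0.29, 0.11), and a fit with no dye effect those of Atp5g1 (0.64) and Sdhd (0.33). Ribosome biogenesis genes rose in 24 of 40 cases and fell in 1 (29 and 2 adjusted over the list alone, median 0.26, adjusted p = 1.6e-15, estimated 0.00013), with Srm at 0.70 ± 0.060 and Bop1 at 0.54 ± 0.044. Of the G1 and S phase genes 21 rose and 0 fell (22 and 0 adjusted over the list alone, median 0.37, adjusted p = 2.1e-18, estimated 1.3e-06), with Pcna at 0.69 ± 0.054 and Mcm4 at 0.68 ± 0.052. The G2 and M phase list was not called, with 5 genes higher and 1 lower, the same counts adjusted over the list alone (median 0.043, adjusted p = 0.082). Without replicate 1 or 2 it was called as higher (adjusted p = 0.049 and 0.046), and so it was with median centring (0.0055), all 3 chosen after the data were seen. Heat shock and unfolded protein response genes rose in 13 cases and fell in 1 (15 and 1 adjusted over the list alone, median 0.29, adjusted p = 9.1e-12, estimated 5.9e-05).

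The genes at the centre of the series, those of glutamine metabolism, autophagy and FOXO, were compared in both lines. Glul, which makes glutamine from glutamate and ammonia and is a FOXO target, fell at 240 min to -0.86 ± 0.046 in the PI3K line (1.82-fold lower) and to -0.79 ± 0.046 in the PKB line (1.73-fold lower). Its values per array ran from -0.94 to -0.72 and from -0.87 to -0.68. The fall was late: at 15, 30 and 60 min Glul in the PI3K line stood at 0.020, 0.076 and 0.019, none called, and at 120 min at -0.22 ± 0.046 (adjusted p = 0.0013). It was called in the PKB line from 60 min on (-0.25 ± 0.046, adjusted p = 0.00051) and stood at -0.27 at 120 min. The calls before 240 min were lost with median centring, where the falls were no smaller (-0.27, adjusted p = 0.28, in the PI3K line at 120 min, -0.31 and -0.31, 0.31 and 0.17, in the PKB line at 60 and 120 min), and that in the PI3K line also without replicate 4 (-0.18, 0.07). A second, dimmer Glul probe was not called at 240 min. Glul is named by the subject of the series, so its place on the FOXO and glutamine lists is not independent evidence of their direction.

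Among 50 measured FOXO targets, 12 fell and 2 rose in the PI3K line at 240 min, and 14 fell and 2 rose in the PKB line. Adjusted over the list alone the counts were 13 lower and 2 higher, and 15 and 2. Camera called the list lower in both lines (adjusted p = 0.0016 and 1.2e-06, estimated 0.0015 and 2.4e-05), although most members were not called and the medians were -0.031 and -0.052 (-0.055 to -0.013 and -0.076 to -0.035 when 1 replicate was left out). Those that fell in both lines included, with the PI3K line first, Bbc3 (-0.94 ± 0.086 and -1.56), Pink1, a kinase of mitochondrial quality control (-0.75 ± 0.056 and -1.05), the PI3K inhibitor Pik3ip1 (-0.90 ± 0.077 and -0.83), Mxi1 (-0.86 ± 0.060 and -0.78) and Trp53inp1 (-0.59 ± 0.054 and -0.68). The glucose-uptake inhibitor Txnip (-0.35 ± 0.079 and -1.18), the stress sensor Sesn1 (-0.63 ± 0.059 and -0.18), Cited2 (-0.37 and -0.30) and the cell cycle inhibitor Cdkn1a (-0.24 and -0.32) were called lower as well. Sod2, the mitochondrial superoxide dismutase, rose in both (0.34 ± 0.052 and 0.23). Calls lost were those of Sesn1 in the PKB line under several alternatives (-0.12, adjusted p = 0.48, without replicate 1), of Txnip in the PI3K line with median centring (-0.34, 0.078), and of Cdkn1a in both with median centring (-0.20 and -0.21, 0.32 and 0.3) and with single replicates left out. Cited2 and Cdkn1a in both lines and Sesn1 and Sod2 in the PKB line were not called with no dye effect (adjusted p = 0.32 and 0.62, 0.38 and 0.12, 0.55 and 0.17), nor in the PKB line were Cited2 without replicate 1 (0.063) and Sod2 without replicate 2 (0.054). The FOXO list was called lower from 15 min on in the PKB line (adjusted p = 0.036, estimated 0.035), with 4 genes lower at 15 min and 9 at 60 min. It was not called in the PI3K line before 240 min (2 lower at 60 min and 9 at 120 min, adjusted p = 0.077 at 120 min). The list lay higher in the PI3K line than in the PKB line at 30 min (adjusted p = 0.003, estimated 0.0023) and 60 min (0.0018, estimated 0.0021), and was not called at 240 min (0.3). The lines have separate t0 RNAs, and at the early times a property of those RNAs was not separated from an earlier response to PKB.

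Autophagy genes fell in both lines. Of 36 genes, 16 fell and 3 rose after 240 min of PI3K activation (median -0.14, adjusted p = 1.1e-05, estimated 0.0032), and 15 fell and 1 rose after PKB activation (median -0.096, adjusted p = 7.0e-08, estimated 0.00041). Adjusted over the list alone, 19 fell and 3 rose, and 16 fell and 3 rose. The autophagosome protein Map1lc3b fell to -0.72 ± 0.042 and -0.45, and its relatives Gabarapl1 to -0.26 ± 0.052 and -0.65 and Gabarapl2 to -0.57 ± 0.041 and -0.15. The cargo receptor Sqstm1 fell to -0.70 ± 0.074 and -0.84, Bnip3 to -0.40 ± 0.083 and -1.21, and its relative Bnip3l to -0.23 and -0.46. In the PKB line Bnip3 stood near its value at 240 min from 15 min on. The initiating kinase Ulk1 (-0.39 and -0.26), the lipid kinase Pik3c3 (-0.43 and -0.44), Wipi1 (-0.39 and -0.50), Atg2a (-0.42 and -0.65) and Atg9a (-0.24 and -0.46) were lower too. So were D14Ertd436e, the platform's name for Atg14 (-0.64 and -0.50), and 9430023L20Rik, its name for Atg101 (-0.24 and -0.22), while Tmem49, now Vmp1, rose in both (0.28 and 0.26). The dimmer probes of Atg2a and Atg9a were not called. Without 1 replicate or another the calls of Atg9a (-0.16, adjusted p = 0.2, without replicate 2) and Bnip3l (-0.21, 0.15, without replicate 3) ended in the PI3K line. In the PKB line those of Ulk1 (-0.21, 0.14, without replicate 3), 9430023L20Rik (-0.16, 0.061, without replicate 3), Gabarapl2 (-0.13, 0.13, without replicate 4) and Tmem49 (0.22, 0.1, without replicate 4) did, and Gabarapl2 stood at -0.043 (adjusted p = 1) with median centring. Ulk1, Wipi1, 9430023L20Rik and Tmem49 in both lines, and Bnip3, Gabarapl1 and Atg2a in the PI3K line (adjusted p = 0.14, 0.096 and 0.14), were not called with no dye effect. The list was called lower in the PKB line from 60 min on with both correlations (at 60 min adjusted p = 0.00021, estimated 0.01). In the PI3K line the call at 120 min was lost with the estimated one (adjusted p = 0.03, and adjusted p = 0.16 with an estimated correlation). The lines did not differ at 240 min beyond the error of the list (adjusted p = 0.87).

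Apart from Glul, more genes of glutamine and glutamate metabolism rose than fell. At 240 min 11 of 33 rose and 6 fell in the PI3K line, 15 and 6 adjusted over the list alone (median 0.089, adjusted p = 0.0086, but adjusted p = 0.14 with an estimated correlation). In the PKB line 15 rose and 3 fell, 17 and 3 adjusted over the list alone (median 0.13, adjusted p = 3.5e-05, estimated 0.013). The glutamine-using enzymes of nucleotide synthesis Ctps (0.99 ± 0.088 and 0.72), Ppat (0.81 ± 0.054 and 0.20), Cad (0.74 ± 0.056 and 0.20) and Gmps (0.38 ± 0.044 and 0.56) rose in both lines. Phgdh, the first enzyme of serine synthesis (0.89 ± 0.095 and 0.62), asparagine synthetase Asns (0.34 ± 0.072 and 0.67), Got1 (0.36 and 0.45), the transporter Slc38a1 (0.38 and 0.45) and Gclc, which starts glutathione synthesis (0.34 and 0.23), rose as well. The glutamine transporter Slc1a5 rose in the PI3K line (0.47 ± 0.048) and stood at -0.17 ± 0.048 in the PKB line, and the dehydrogenase Idh2 at -0.18 ± 0.062 and 0.27. These last 3 calls did not hold under every alternative: Slc1a5 in the PKB line stood at -0.067 (adjusted p = 0.99) with median centring, Idh2 at -0.16 (0.23) without replicate 1 in the PI3K line and at 0.16 (0.15) without replicate 4 in the PKB line. With no dye effect Got1 and Gclc lost their calls in both lines and Asns and Idh2 (adjusted p = 0.37 and 0.33) in the PI3K line and Slc1a5 and Cad (0.41 and 0.074) in the PKB line, and Ppat and Cad did in the PKB line without replicate 3 (0.11 and 0.081). Cad has 4 dimmer probes, none of which was called.

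**Figure D1:**
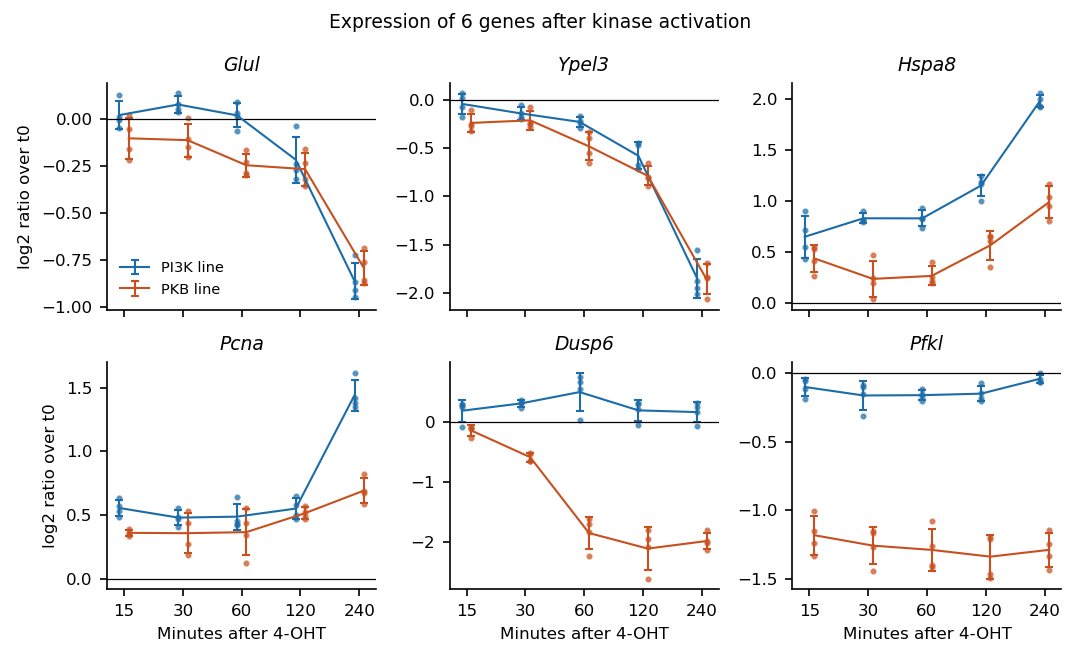
Log2 ratio of time point over t0 (y axis) against minutes after 4-OHT (x axis, spaced by time point) for 6 genes in the PI3K and PKB lines. Small points are the 4 arrays of a group, lines join their means and bars are SDs; at 240 min Glul stood at -0.86 and -0.79, and Dusp6 at 0.17 and -1.98.

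The number of probes called in the PI3K line grew over the time course. At 15 min 203 probes were called higher and 107 lower. Of the genes with the same sign on all 4 arrays, the rule for naming genes here and at the later times, the highest were Timeless, a replication fork protein (0.73 ± 0.11, with an SD of 0.63 over the 4 arrays), Hspa8 (0.65 ± 0.065), the protease Gzmb (0.58 ± 0.067) and Pcna (0.56 ± 0.054). Timeless stood at 1.68 in replicate 2 and at 0.39 to 0.45 in the others, so its rank rests on that array. The lowest were the histone genes Hist1h2bc (-0.83 ± 0.097), Hist1h1c (-0.71 ± 0.099) and Hist1h2bf (-0.50 ± 0.076) and the monoamine transporter Slc18a2 (-0.53 ± 0.060). At 30 min, with 204 higher and 180 lower, Gzmb (0.95 ± 0.067), Hspa8 (0.83 ± 0.065), Baiap2, which shapes actin protrusions (0.72 ± 0.059), and the cytoplasmic actin Actg1 (0.67 ± 0.035) led. Hist1h2bc (-0.60 ± 0.097), Hist1h2an (-0.59 ± 0.061), the adaptor Sla2 (-0.57 ± 0.071) and Hist1h1c (-0.52 ± 0.099) were lowest. At 60 min (476 and 361) Gzmb (1.08 ± 0.067), Eif5 (1.07 ± 0.065), Actg1 (0.92 ± 0.035) and Hspa8 (0.83 ± 0.065) were highest and Zkscan14 (-0.78 ± 0.062), Hist1h2bc (-0.60 ± 0.097), Sla2 (-0.58 ± 0.071) and Ccl9 (-0.58 ± 0.077) lowest. At 120 min 1241 and 1056 probes were called, led by Actg1 (1.34 ± 0.035), Eif5 (1.33 ± 0.065), Tuba4a (1.23 ± 0.048) and Hspa8 (1.15 ± 0.065), and at the other end Cir1 (-1.06 ± 0.047), Hbp1 (-1.01 ± 0.069), the splicing kinase Clk1 (-1.01 ± 0.067) and Cmas (-0.98 ± 0.034). Over the 5 times together 4540 probes changed. The early counts depended on the normalization and on the arrays that share a fit. With median centring 16 probes were higher and 17 lower at 15 min and 10 and 93 at 30 min. A fit of each group's own 4 arrays, which also takes the dye effect from these alone, called 20 and 57. With a dye effect for each line, added after the data were seen, the counts were 501 and 714. Leaving out 1 replicate gave 144 to 207 calls at 15 min and 179 to 216 at 30 min. Median centring ended the calls of Timeless, Gzmb and Pcna at 15 min (0.56, 0.55 and 0.52, adjusted p = 0.24, 0.9 and 0.12), Gzmb, Baiap2 and Actg1 at 30 min (0.71, 0.57 and 0.42, adjusted p = 0.13, 0.062 and 0.067) and Ccl9 at 60 min (-0.59, 0.19), and a fit with no dye effect those of Hspa8 at 15 min (0.28) and of the histone genes at 15, 30 and 60 min.

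In the PKB line more probes were lower than higher up to 60 min. The excess was smaller when only the brightest probe of each gene was counted. Lower and higher were then 145 and 73 at 15 min, 181 and 133 at 30 min and 352 and 333 at 60 min. Over all probes 383 were lower and 116 higher at 15 min. Pfkl (-1.18 ± 0.057), Bnip3 (-1.15 ± 0.083), Hist1h1c (-1.09 ± 0.099) and Mif (-0.97 ± 0.045) were lowest then and again at 30 min (-1.26 ± 0.057, -1.10 ± 0.083, -0.94 ± 0.099 and -0.93 ± 0.045). The rises were smaller, with Hspa8 (0.44 ± 0.065), Pcna (0.36 ± 0.054), Uhrf1 (0.36 ± 0.079) and Fdps, an enzyme of isoprenoid synthesis (0.34 ± 0.056), highest at 15 min. At 30 min (193 higher, 414 lower) they were the tubulin Tuba1b (0.39 ± 0.054), Pcna (0.36 ± 0.054), the replication factor Gins1 (0.35 ± 0.049) and Lin7b (0.34 ± 0.094, adjusted p = 0.045, and not called without replicate 1, 2 or 3). At 60 min (477 and 624) Dusp6 had fallen to -1.85 ± 0.10, below Pfkl (-1.29 ± 0.057), Bnip3 (-1.18 ± 0.083) and Hist1h1c (-1.09 ± 0.099). The highest were then Olfr1019 (0.64 ± 0.16, with an SD of 0.98, and not called without replicate 2), the antioxidant enzyme Srxn1 (0.56 ± 0.051), Cycs (0.55 ± 0.13) and the exosome subunit Exosc6 (0.55 ± 0.055). Cycs was not called without replicate 2, 3 or 4 (0.54, 0.51 and 0.52, adjusted p = 0.064, 0.065 and 0.1), and with no dye effect neither were Hspa8 at 15 min (1), Lin7b at 30 min (1) and Olfr1019, Cycs and Exosc6 at 60 min (0.46, 1 and 0.073). At 120 min (1145 and 1235, but 1328 and 1291 with the deposited log2 ratios) Dusp6 stood at -2.11 ± 0.10, Bbc3 at -1.44 ± 0.086, Pfkl at -1.34 ± 0.057 and Hbp1 at -1.30 ± 0.069, against Srxn1 at 0.83 ± 0.051, Cdr2 at 0.74 ± 0.087, Mid1ip1 at 0.73 ± 0.099 and the phosphatase Pgp at 0.70 ± 0.057. Over the 5 times together 4223 probes changed. With median centring the rises of Hspa8, Pcna, Uhrf1 and Fdps at 15 min (0.24, 0.20, 0.25 and 0.23, adjusted p = 0.65, 0.72, 0.48 and 0.6) and of Tuba1b, Pcna and Lin7b at 30 min (0.33, 0.33 and 0.29, adjusted p = 0.35, 0.57 and 0.49) were not called, and 7 probes were higher and 311 lower at 15 min, 18 and 236 at 30 min, 69 and 415 at 60 min and 369 and 726 at 120 min.

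**Figure D2:**
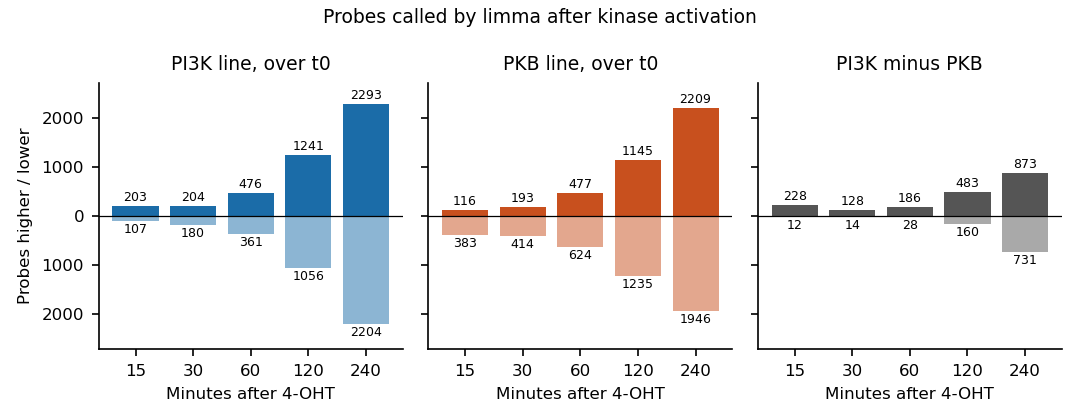
Probes called by limma (adjusted p under 0.05, of 31769) at each time after 4-OHT, in the PI3K line, the PKB line and for the difference between them. Bars above 0 count probes that were higher and bars below 0 those that were lower; at 240 min the PI3K line had 2293 and 2204 and the difference 873 and 731.

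The gene lists moved at different times. Ribosome biogenesis genes were first called with both correlations at 60 min, with 14 higher and 0 lower in the PI3K line (median 0.15, estimated adjusted p = 2.1e-05) and 11 and 1 in the PKB line (median 0.12, estimated 0.0013). At 15 min 1 gene of the list was higher in each line. G1 and S phase genes were already higher at 15 min, 12 in the PI3K line and 11 in the PKB line, 15 and 15 adjusted over the list alone (medians 0.14 and 0.19, estimated adjusted p = 3.2e-08 and 1.3e-06). Their median in the PI3K line then stayed near that level (0.14, 0.097 and 0.17 at 30, 60 and 120 min) before 0.69 at 240 min. The G2 and M phase list began higher in the PI3K line, with 7 genes higher at 15 min and 20 adjusted over the list alone (median 0.19, estimated adjusted p = 6.1e-08). Its median was 0.048 at 60 min (adjusted p = 0.033, and adjusted p = 0.17 with an estimated correlation) and -0.020 at 120 min, not called, ahead of its fall at 240 min. Its median in the PKB line was 0.047 at 15 min (adjusted p = 0.0079, and adjusted p = 0.08 with an estimated correlation) and 0.10 at 30, 60 and 120 min, each called with both correlations. Glycolysis genes in the PKB line were at their low level at 15 min, when 12 of 22 were lower than at t0 (median -0.33, estimated adjusted p = 7.5e-08), and had medians of -0.29, -0.32, -0.35 and -0.23 at the later times. Immediate early genes in the PI3K line rose at 60 min, 6 of 35 (estimated adjusted p = 0.027), among them Myc (0.43 ± 0.072) and Dusp6 (0.51 ± 0.10). Both calls were lost with no dye effect (adjusted p = 1 and 0.14), and that of Dusp6 also without replicate 1 or 4 (0.48 and 0.44, adjusted p = 0.084 and 0.12). In the PKB line 5 fell at 60 min and 1 rose (estimated 5.9e-05), with Myc at -0.85 ± 0.072.

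**Figure D3:**
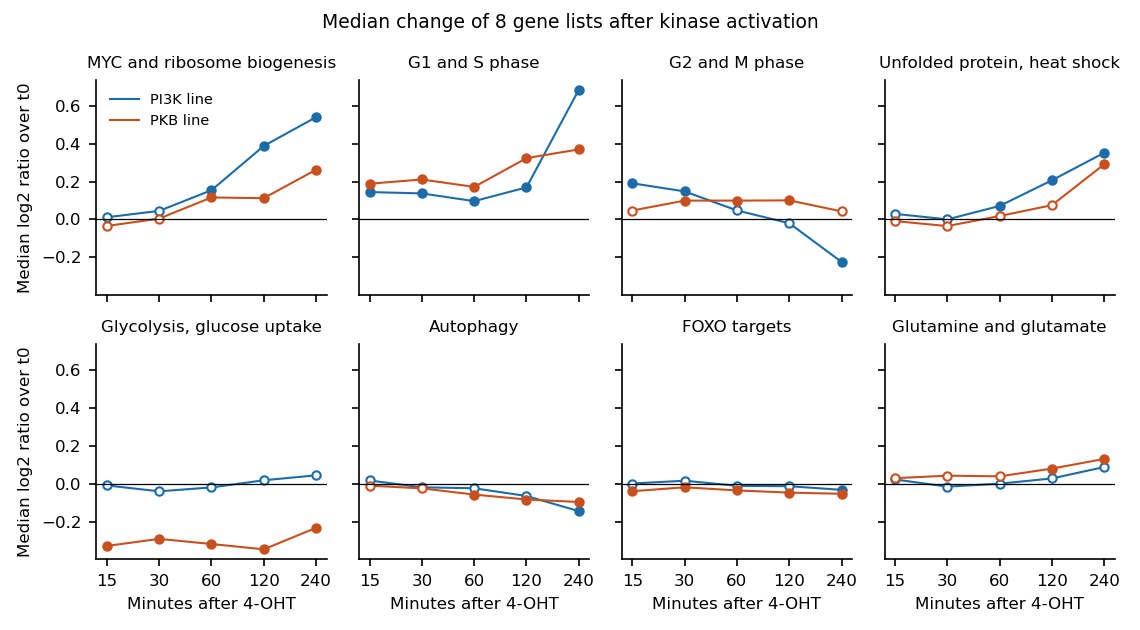
Median log2 ratio over t0 (y axis) of the measured genes of 8 lists against minutes after 4-OHT (x axis, spaced by time point) in the PI3K and PKB lines; filled points mark medians whose list camera called with an estimated correlation. The ribosome biogenesis median reached 0.54 and 0.26 at 240 min, and glycolysis in the PKB line lay at -0.33 by 15 min.

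The test of the difference between the lines asks which probes responded differently to PI3K and to PKB. At 240 min 873 probes were higher in the PI3K line than in the PKB line and 731 lower, after 228 and 12 at 15 min (56 and 6 of them the brightest probe of their gene), 128 and 14 at 30 min, 186 and 28 at 60 min and 483 and 160 at 120 min. The widest difference at 240 min was Dusp6, 2.15 ± 0.14, from 0.17 in the PI3K line and -1.98 in the PKB line. F2r (1.89 ± 0.081) and Etv5 (1.65 ± 0.15) likewise fell in the PKB line and not in the PI3K line (0.11 and 0.27, where Etv5 was called higher with the deposited log2 ratios, 0.25, adjusted p = 0.016). Tuba8 (1.80 ± 0.23) stood at 1.05 against -0.75, and Eif5 (1.56 ± 0.092) at 1.55 against -0.0025. The dimmer Etv5 probe was not called. In the other direction were Itsn1 (-1.36 ± 0.10), Fgf15 (-1.30 ± 0.12), Tspan8 (-1.26 ± 0.11), the chloride transporter Clcn3 (-1.06 ± 0.088) and the condensin subunit Smc4 (-0.90 ± 0.14). At 15 and 30 min the glycolytic enzymes Pfkl (1.08 ± 0.081 and 1.10 ± 0.081) and Aldoa (1.07 ± 0.11 and 1.06 ± 0.11) were the highest of the genes named. The lowest were Itsn1 (-0.51 ± 0.10) and Phlpp1, a phosphatase that acts on PKB (-0.46 ± 0.10), at 15 min, and Hist1h2an (-0.50 ± 0.087) and Itsn1 (-0.42 ± 0.10, adjusted p = 0.043) at 30 min. At 60 min Dusp6 (2.35 ± 0.14) and Myc (1.27 ± 0.10) were highest and Urgcp (-0.64 ± 0.16, adjusted p = 0.045) and Hist1h2an (-0.56 ± 0.087) lowest. At 120 min these places were taken by Dusp6 (2.31 ± 0.14) and F2r (1.51 ± 0.081), and by Itsn1 (-0.71 ± 0.10) and Smc4 (-0.70 ± 0.14). Without 1 replicate or another the calls of Itsn1 and Phlpp1 at 15 min, Itsn1 and Hist1h2an at 30 min, Urgcp at 60 min (-0.36, adjusted p = 0.26, without replicate 1) and Smc4 at 120 min (-0.57, 0.11, without replicate 4) were lost. Median centring ended those of Hist1h2an at 60 min (-0.50, adjusted p = 0.13), Itsn1 at 120 min (-0.77, 1) and 240 min (-1.37, 0.098) and Tspan8 (-1.20, 0.37), and a fit with no dye effect those of Etv5 (adjusted p = 0.064) and Smc4 (0.77) at 240 min, the PKB value of Tuba8 (0.066), Smc4 at 120 min and all the lower genes named at 15, 30 and 60 min. Counts from 15 to 240 min were 74, 49, 74, 302 and 1055 without replicate 4 and 60, 16, 57, 156 and 372 with median centring. Each kinase was carried by 1 line here, so kinase and line cannot be separated.

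Several lists differed between the lines at 240 min. Ribosome biogenesis genes were higher with PI3K by a median of 0.29 (17 higher, 0 lower, 22 and 0 adjusted over the list alone, estimated adjusted p = 5.9e-05). So were G1 and S phase genes, by 0.34 (13 and 1, 17 and 2 adjusted over the list alone, estimated 4.9e-07), and glycolysis genes, by 0.40 (11 and 0, 12 and 0 adjusted over the list alone, estimated 2.3e-05). G2 and M phase genes were lower, by -0.36 (15 lower and 0 higher, 21 and 0 adjusted over the list alone, estimated 4.9e-07), and so were oxidative phosphorylation genes, by -0.18 (10 and 0, 13 and 1 adjusted over the list alone, estimated 2.3e-05). In the PI3K line the oxidative phosphorylation list itself was not called (4 higher, 7 lower, the same adjusted over the list alone, adjusted p = 0.64). The glycolysis list was not called there either, and its difference already stood at a median of 0.19 at 15 min. Its low level in the PKB line cannot be told from a property of the t0 RNA. Immediate early genes were higher with PI3K (6 and 0, 8 and 0 adjusted over the list alone, estimated 0.0005): Myc stood at 0.63 ± 0.072 against -0.40 (the latter not called with no dye effect, adjusted p = 0.45), and the AP-1 subunit Fosl1 at 0.77 ± 0.085 against -0.096. At 240 min 4 of these genes had risen and 4 fallen in the PI3K line (adjusted p = 0.64) and 7 had fallen in the PKB line (estimated 0.0018), among them Ier3 (-0.44 and -0.81). Of the interleukin-3 and STAT5 list 4 of 23 were higher and 0 lower with PI3K (4 and 1 adjusted over the list alone, estimated 0.014). Cyclin Ccnd2 reached 1.15 ± 0.093 there, the differentiation inhibitor Id1 0.87 ± 0.054 and Ccnd3 0.46 ± 0.070, against 0.063, -0.013 and 0.045 in the PKB line (Ccnd3 0.21, adjusted p = 0.035, without replicate 4). Within the lines that list was not called (5 higher and 5 lower with PI3K, 0 and 4 with PKB, adjusted p = 0.58 and 0.054).

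Many of the changes since t0 were common to both lines. At 240 min 1380 probes were called higher in both and 939 lower in both, where independent lists of these sizes would share 159 and 135. Another 119 were called in opposite directions, where independence gives 294. Across the 31769 probes, which are not independent replicates, the log2 ratios of the lines correlated with r = 0.625. It was 0.22 at 15 min, 0.267 at 30 min, 0.415 at 60 min and 0.513 at 120 min. The lines share no t0 RNA. The genes lowest in both were Ypel3, Hist1h1c, Cmas (-1.47 and -1.21), Hbp1, Wdr45, an autophagy protein (-1.09 ± 0.065 and -1.20), Tcp11l2 (-1.06 in the PI3K line), Abtb1 (-0.99 ± 0.044 and -1.22) and Bbc3. The highest in both were Cycs, Dynll1 (1.02 in the PI3K line), Ndufaf4 (1.37), Hsph1, Hspa8, Tubb2c (0.96), Tuba4a and Psmc3ip (1.20). With no dye term 1051 probes were shared.

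**Figure D4:**
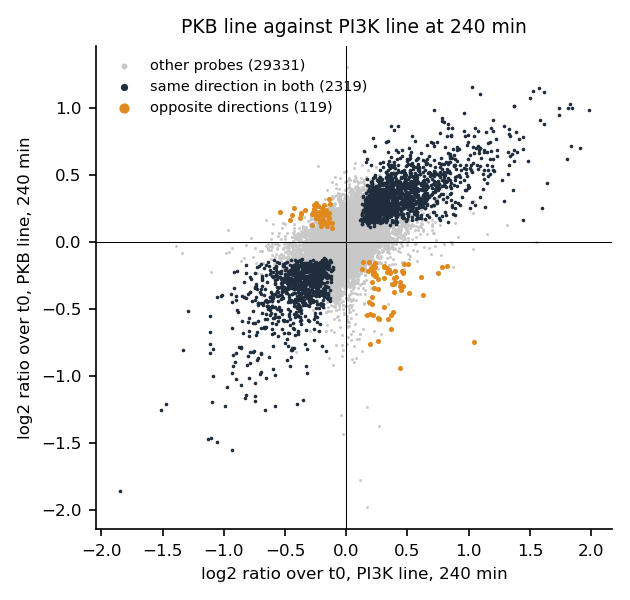
Log2 ratio at 240 min over t0 in the PKB line (y axis) against the PI3K line (x axis) for 31769 probes. Dark points are the 1380 probes higher and 939 lower in both lines, orange points the 119 called in opposite directions; r across probes was 0.625.

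Within each line 240 min was also set against 15 min, a comparison in which the t0 RNA drops out. In the PI3K line 1405 probes were higher at 240 min and 1277 lower, and in the PKB line 1033 and 668. Ribosome biogenesis genes were higher in both (medians 0.49 and 0.30, 28 and 19 higher, estimated adjusted p = 5.5e-07 and 0.00013), as were G1 and S phase genes (0.48 and 0.21, 20 and 8 higher, estimated 1.6e-07 and 0.0011). Autophagy genes were lower (-0.15 and -0.12, 10 and 10 lower, estimated 0.0034 and 0.003), and so were FOXO targets (9 and 10 lower, estimated 0.0006 and 0.00014). G2 and M phase genes fell between these times in the PI3K line (-0.42, 20 of 26, estimated 1.6e-07) and were not called in the PKB line (0.025, adjusted p = 0.93). The glycolysis list in the PKB line was not called (0.037, adjusted p = 0.66). Glutamine metabolism genes were higher by the preset correlation in both lines (0.062 and 0.11), but adjusted p = 0.21 and 0.077 with an estimated correlation. Because the 5 arrays of a series share their t0 RNA, ratios of different times are related by chance. Across probes the 15 and 240 min ratios correlated with r = 0.211 in the PI3K line and 0.3 in the PKB line, where simulated series with no change gave 0.289 and 0.29. The covariances were 0.00308 and 0.00433 against 0.00167 in the simulation. The simulation used the correlation within series of the fit with 1 dye effect (0.289), which was 0.118 with a dye effect for each line. It can therefore overstate what a shared t0 RNA gives. With the times taken from different series, which share no t0 RNA, r was 0.14 and 0.12 in the PI3K line. It was 0.29 and 0.24 in the PKB line. Without replicate 1 or 3 the PKB count was 1072 or 1122.

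Of the kinases' own genes, Akt1, which encodes PKB, rose at 240 min in the PI3K line (0.73 ± 0.052) and the PKB line (0.39 ± 0.052). Pik3ca, which encodes a catalytic PI3K subunit, fell in the PKB line (-0.35 ± 0.077, adjusted p = 0.00091) and stood at -0.15 ± 0.077 in the PI3K line (adjusted p = 0.29). The first call was lost without replicate 4 (-0.24, adjusted p = 0.1) and with median centring (-0.30, 0.46), and in the PI3K line Pik3ca was called lower with print-tip loess (-0.22, 0.039) and with the deposited log2 ratios (-0.21, 0.048). Esr1, the oestrogen receptor, was not called at any time and stood at 0.0061 and 0.039. No probe is known here to separate the fusion transcripts from the cells' own. In the PI3K pathway list 3 of 35 genes rose and 5 fell in the PI3K line (3 and 6 adjusted over the list alone, adjusted p = 0.35). After PKB activation 1 rose and 7 fell, the same adjusted over the list alone (adjusted p = 0.036, and adjusted p = 0.055 with an estimated correlation). Phlpp1 (-0.86 ± 0.072 and -0.14) and the receptor Igf1r (-0.40 and -0.66) were among them. Phlpp1 was not called in the PKB line except in a fit of that line alone (adjusted p = 0.017). Igf1r lost its call without replicate 3 in the PI3K line (-0.36, adjusted p = 0.083) and with no dye effect in both (0.71 and 0.15).

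Markers of B-lineage progenitors, the lineage of these cells, and of other cell types were not called as lists in either line at the last time point. Single members moved. In the B-lineage progenitor list 1 of 17 genes was higher and 2 lower in the PI3K line, and 1 and 1 in the PKB line, the same adjusted over the list alone (adjusted p = 0.64 and 0.56). The leukocyte phosphatase Ptprc fell to -0.80 ± 0.060 and -0.67, and the transcription factor Tcf3 rose to 0.39 and 0.30. Of 19 myeloid and mast cell genes 2 rose and 1 fell with PI3K, 3 and 1 adjusted over the list alone, and 0 and 2 with PKB, the same adjusted over the list alone (adjusted p = 0.64 and 0.11). Gzmb stood at 0.87 ± 0.067 in the PI3K line and Gata2 at -0.41 ± 0.052 in the PKB line. Of 17 T cell, erythroid and fibroblast genes 1 rose and 2 fell in each line, the same adjusted over the list alone (adjusted p = 0.44 and 0.43), with the erythropoietin receptor Epor at -0.44 ± 0.052 in the PI3K line.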

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

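The values of single arrays were searched with Dixon's test for 1 array far from the other 3, and the lines were compared by rules fixed before; the bounds used below to weigh the 3 patterns, and all tests on them but the test of dye bias, were chosen only after the patterns had been seen. Among 295 groups of 4 arrays behind the genes named, 14 had such an array, where 5.25% of groups of normal values do. The widest were Timeless in the PI3K line at 15 min, with 1.68 in replicate 2 against 0.39 to 0.45 in the others, and Olfr1019 in the PKB line at 60 min, with 2.10 in replicate 2 against 0.088 to 0.25. Without replicate 2 Timeless stood at 0.40 and was still called (limma adjusted p = 0.00076), while Olfr1019 stood at 0.14 and was not (0.27). In the PKB line at 240 min replicate 4 stood apart for Sqstm1 (-1.40), Idh2 (0.60), Atp5g1 (0.65), Gmps (0.67), Slc1a5 (-0.26) and Gata2 (-0.18), replicate 3 for Pik3c3 (-0.23), Slc38a1 (0.58) and Wdr45 (-1.41), and replicate 2 for Atf4 (0.62). In the PI3K line replicate 3 stood apart for Hist1h2bc at 15 min (-0.51) and Scarb2 at 240 min (-0.73). These arrays were kept.

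The lines differed, PI3K minus PKB, most widely in Dusp6 (2.15 at 240 min, 2.35 at 60 min and 2.31 at 120 min), F2r (1.89 at 240 min and 1.51 at 120 min), Tuba8 (1.80), Etv5 (1.65) and Eif5 (1.56). In the other direction stood Itsn1 (-1.36 at 240 min, -0.51 at 15 min, -0.42 at 30 min and -0.71 at 120 min), Fgf15 (-1.30), Tspan8 (-1.26), Clcn3 (-1.06) and Smc4 (-0.90 at 240 min and -0.70 at 120 min). Early differences were those of Pfkl (1.08 at 15 min and 1.10 at 30 min), Aldoa (1.07 and 1.06), Phlpp1 (-0.46 at 15 min), Hist1h2an (-0.50 at 30 min and -0.56 at 60 min), Myc (1.27 at 60 min) and Urgcp (-0.64 at 60 min). Of the lists, glycolysis (median 0.19), the hypoxia response (0.040), G2 and M phase genes (0.14) and oxidative phosphorylation (-0.062) differed at 15 min. At 240 min the medians were 0.40 for glycolysis, 0.10 for the hypoxia response, 0.34 for G1 and S phase genes, -0.36 for G2 and M phase genes and -0.18 for oxidative phosphorylation. They were 0.29 for ribosome biogenesis, 0.093 for ribosomal proteins, -0.13 for cholesterol synthesis, 0.044 for immediate early genes and 0.068 for the interleukin-3 and STAT5 list. Each line is a clone, so these differences may belong to the clone or to the kinase, and a second clone of each kind would separate these. The arrays differed as well, with median Cy5 signals of 80.4 to 117 units in the PI3K line and 120 to 207 units in the PKB line. Line and array signal cannot be separated here either.

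The first pattern weighed is the low level of glycolysis genes in the PKB line by 15 min, which then stayed flat. One explanation is a t0 RNA with raised glycolysis genes, for example from the handling of the t0 cells, which predicts no further change: the list median at 240 min minus 15 min was 0.037, so this cannot be told from a true fast fall. For Pfkl to fall so far in 15 min its mRNA half-life could be at most 12.7 min even if transcription had stopped at once. A single deviating series is excluded, since 4 of 4 series had list medians under -0.1 at 15 min (-0.35 to -0.18). Handling or 4-OHT acting on both lines alike cannot be the whole explanation, since the lines differed by a median of 0.19 at 15 min. A smaller part shared by both lines is not excluded.

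The second is the rise of G1 and S phase genes by 15 min in both lines. If these genes were low in the t0 RNA, the later values should not differ from those at 15 min: the list median at 60 min minus 15 min was -0.068 in the PI3K line and 0.0063 in the PKB line. The values at 15 to 60 min therefore cannot be told from a property of the t0 RNA. For 240 min it cannot be the whole explanation, since the medians at 240 min minus 15 min were 0.48 and 0.21. A part of the values at 240 min as large as those at 15 min may still belong to the t0 RNA.

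The third is the fall of G2 and M phase genes in the PI3K line at 240 min. High values in the t0 RNA do not account for it, because the list also fell against 15 min (-0.42). Dye bias of the probes is excluded, with list medians of -0.20 and -0.26 in the 2 dye orientations when no dye effect was removed. A single deviating series is excluded, with 4 of 4 series under -0.1 (-0.32 to -0.21).

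Whether other groupings of the arrays give as many calls was examined by turning the sign of whole series and counting calls again. With 8 splits per line no share under 0.05 can be reached, so these splits cannot settle the counts against t0. The real count was 310, 384, 837, 2297 and 4497 in the PI3K line from 15 to 240 min, and the highest of the other splits 4472, 5489, 3202, 4359 and 4735. For any time they were 4540 and 7031. The PKB line had a real count of 499, 607, 1101, 2380 and 4155 against a highest other of 3969, 5505, 3408, 2904 and 3771, and for any time 4223 and 6239. As many calls as in the real split were found in 2 of 8 splits, and at 240 min in the PKB line in 1 of 8. The highest other split is the one that turns series 2 and 4 and so undoes the dye orientation, and it counts what is left of the dye effect in that line. With a dye effect for each line 501 probes were called in the PI3K line at 15 min and 714 at 30 min. Shared calls at 240 min numbered 2319, and 308 in the highest of the other 62 splits that could be fitted (1 of 63 reached the real value). The PI3K against PKB counts of 240, 142, 214, 643 and 1604 were each reached by 1 of 35 splits of the 8 arrays, with highest other counts of 48, 1, 1, 1 and 72. For 240 min against 15 min, 2682 and 1701 probes compare with 3 and 55 in the highest other of 8 splits (1 of 8 reached the real value in each line).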

How the results depend on the processing

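The dye effect per line, the use of 240 min against 15 min on the lists and every alternative on the medians of the G1 and S phase, G2 and M phase, ribosome biogenesis and glycolysis lists were chosen only after the data had been seen; all other alternatives were fixed before. Counts at 15 to 60 min depend on normalization, dye effect and the arrays that share a fit. Those at 240 min depend on the dye effect and, above all for the difference and the lower probes, on normalization. Of 321 pairs of gene and comparison named, 225 kept their call, or their lack of one, under every alternative run for them. The call was lost by 51 with median centring and by 61 with no dye effect. No pair called in the main fit or in the alternative turned direction, and changes of sign without a call were not counted. In a replicate block (random), the PI3K line had 4508 calls at 240 min, and in a paired analysis with fixed blocks 240 min against 15 min had 2368 (PI3K) and 1165 (PKB); a replicate block of series with the same number gave 1641 for the difference at 240 min. Slide batch was not run because the files give none.

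Counts below run from 15 to 240 min unless a time is named, in the order PI3K line, PKB line, difference. Median centring: 33, 103, 192 and 1211 to 120 min; 318, 254, 484 and 1095 to 120 min (any time 2712); 60, 16, 57, 156 and 372. It moved the G2 and M phase median in the PKB line to 0.12 (adjusted p = 0.0055). No dye effect: 70, 75, 216, 874 and 2214 (any time 1981); 182, 220, 394, 895 and 1828 (any time 1832); 38, 27, 43, 156 and 483; shared 1051. The group's own arrays: 20, 57, 135 and 1465 to 120 min; 227 at 15 min. At least 1.5-fold: 7, 13, 30, 184 and 632 (any time 647); 45, 46, 45, 119 and 319 (any time 360); 30, 37, 52, 111 and 220; 240 min against 15 min 525 and 232; shared 182. Dye effect per line: 501, 714 and 1375 to 60 min; 1691 at 60 min; 298, 426 and 991 at 30 to 120 min. Offset 16: difference 92 at 30 min and 129 at 60 min. Glutamine list, PI3K line: median 0.089, adjusted p = 0.14 with an estimated correlation.

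Leaving out 1 replicate gave, lowest to highest: PI3K line 144 to 207, 179 to 216 and 445 to 650 to 60 min; PKB line 307 to 406, 348 to 514, 610 to 965 and 1560 to 1861 to 120 min; difference 74 to 200, 49 to 149, 74 to 175, 302 to 538 and 1055 to 1261; PKB 240 min against 15 min 1072 to 1284. The G2 and M phase median in the PKB line ran from 0.0055 to 0.054 (0.039 without replicate 1), and the FOXO median from -0.055 to -0.013 in the PI3K line.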

Other observations

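The lists below were fixed before the data were examined; the test on ERK target genes in the last paragraph was chosen only after the falls of Dusp6 and Etv5 had been seen. Single genes of lipid synthesis and of the amino acid response rose in both lines. At 240 min 10 of 19 cholesterol synthesis genes rose and 0 fell in the PKB line (11 and 1 adjusted over the list alone, median 0.25, camera adjusted p = 8.0e-09, estimated 0.00067). In the PI3K line 7 rose and 3 fell and the list was not called (9 and 3 adjusted over the list alone, median 0.090, adjusted p = 0.078). Sqle, a rate-limiting enzyme of the pathway, reached 0.80 ± 0.066 in the PI3K line and 0.90 ± 0.066 in the PKB line, Sc4mol 0.86 ± 0.062 and 0.80 ± 0.062, and Fdps 0.22 ± 0.056 and 0.78 ± 0.056. Fdps in the PI3K line was not called without replicate 4 (0.14, limma adjusted p = 0.14) or 1 (0.17, 0.15). Tm7sf2, a sterol reductase, fell in the PI3K line (-0.56 ± 0.060). Of 18 fatty acid synthesis genes 8 rose and 1 fell with PI3K (9 and 2 adjusted over the list alone, adjusted p = 0.0061, but adjusted p = 0.11 with an estimated correlation), and 7 and 1 with PKB (7 and 2 adjusted over the list alone, adjusted p = 0.0013, estimated 0.042). Fasn, the fatty acid synthase, reached 0.89 ± 0.072 and 0.58 ± 0.072, the carboxylase Acaca 0.75 ± 0.055 and 0.46 ± 0.055, and the desaturase Scd2 0.71 ± 0.051 and 0.74 ± 0.051. Of 35 genes of the ATF4 and amino acid response 14 rose and 2 fell with PI3K (17 and 2 adjusted over the list alone, adjusted p = 0.00016, estimated 0.0098), and 16 and 4 with PKB (16 and 5 adjusted over the list alone, adjusted p = 3.5e-05, estimated 0.0045). The transcription factor Atf4 stood at 0.57 ± 0.056 and 0.56 ± 0.056, the aminoacyl-tRNA synthetases Mars at 0.71 ± 0.060 and 0.72 ± 0.060 and Tars at 0.53 ± 0.039 and 0.57 ± 0.039, and Pck2, a mitochondrial carboxykinase, fell to -1.05 ± 0.090 and -0.41 ± 0.090. Pck2 in the PKB line was not called with median centring (-0.31, adjusted p = 0.35), nor Fasn there and Tars in both lines with no dye effect (0.068, 0.083 and 0.058).

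NF-kB targets fell, 6 of 24 with PI3K and 0 higher (the same adjusted over the list alone, adjusted p = 0.014, but adjusted p = 0.056 with an estimated correlation), and 5 with PKB and 0 higher (the same adjusted over the list alone, adjusted p = 0.0052, estimated 0.022). The lymphotoxin Ltb stood at -0.43 ± 0.048 and -0.54 ± 0.048, the NF-kB subunit Nfkb1 at -0.37 ± 0.060 and -0.58 ± 0.060, and the inhibitor Nfkbia at -0.52 ± 0.054 in the PI3K line. Of 14 genes of the BCL2 family 2 rose and 2 fell with PI3K and 1 and 3 with PKB, the same adjusted over the list alone, and the list was not called (adjusted p = 0.57 and 0.054). Its pro-apoptotic member Bid fell beside Bbc3 (-0.20 ± 0.044 and -0.45 ± 0.044) and Bad rose (0.19 ± 0.053 and 0.28 ± 0.053). Bad in the PI3K line was not called without replicate 1 (0.15, limma adjusted p = 0.18), nor in either line with no dye effect (1 and 1), and Bid in neither with median centring (-0.18 and -0.35, 0.49 and 0.05). Of 20 lysosome genes 1 rose and 4 fell with PI3K (2 and 5 adjusted over the list alone, adjusted p = 0.24), and 2 and 6 with PKB (2 and 8 adjusted over the list alone, adjusted p = 0.038, but adjusted p = 0.1 with an estimated correlation). The membrane protein Scarb2 stood at -0.62 ± 0.053 and -0.24 ± 0.053, the latter not called with median centring (-0.17, adjusted p = 0.31) or with no dye effect (0.87). Ribosomal protein genes moved little, 1 of 31 higher and 0 lower with PI3K (adjusted p = 0.64) and 4 lower and 0 higher with PKB (adjusted p = 0.018, but adjusted p = 0.07 with an estimated correlation), the same adjusted over the list alone. Rpl23 fell to -0.41 ± 0.039 in the PKB line (-0.29, adjusted p = 0.066, with median centring). Of 23 interferon response genes 2 fell and 2 rose with PI3K (3 and 2 adjusted over the list alone) and 4 and 1 with PKB (5 and 1 adjusted over the list alone), without a call (adjusted p = 0.54 and 0.11). Targets of the oestrogen receptor, which 4-OHT might have driven in both lines, were not called either (3 of 18 higher and 1 lower, and 3 and 2, the same adjusted over the list alone, adjusted p = 0.57 and 0.67). Xbp1, a transcription factor of the unfolded protein response on that list, rose in both (0.43 ± 0.052 and 0.35 ± 0.052).

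Hypothesis: PKB activation lowers the output of the ERK pathway, of which Dusp6 and Etv5 are targets. The test took 8 other measured genes known to follow ERK activity (Phlda1, Spry2, Spry4, Dusp4, Ccnd1, Epha2, Epha4 and Etv4), which should be lower in the PKB line at 240 min. Their median was -0.012, limma called 0 higher and 0 lower (0 at unadjusted p under 0.05), and camera with an estimated correlation gave p = 0.65 (-0.10 for Phlda1 and -0.13 for Dusp4, neither called). At 60 min, when Dusp6 was already low, the median was 0.0062 (0 called, 2 at unadjusted p under 0.05, Phlda1 lower at -0.27 and Ccnd1 higher at 0.12). These 8 genes did not share the falls of Dusp6 and Etv5, but all had dimmer probes than Dusp6 and the test left out 2 called genes that ERK can also induce, Myc (-0.85 at 60 min and -0.40 at 240 min, the latter not called with no dye effect, adjusted p = 0.45) and Ier3 (-0.81 at 240 min). The immediate early list that holds them, and Dusp6 too, was called lower in the PKB line (estimated adjusted p = 5.9e-05 at 60 min and 0.0018 at 240 min), so the hypothesis stays open. Phosphorylated ERK measured over the same times would test it directly.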
